A study of Mus musculus with 6 samples.

How the data were processed

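RNA from 3 control and 3 TBZ samples of cultured E12.5 mouse pancreatic bud was enriched for poly-A transcripts, made into libraries with the NEBNext Ultra RNA kit and sequenced in read pairs. Per the submitters' processing notes, reads were aligned with STAR and counted with HTSeq on mm10, without versions. The deposited table holds 54532 genes. Per the file headers its read count values are 1 column per library with no normalization, and they are whole numbers. The FPKM values were computed by the authors per kilobase of the deposited gene length and per effective library total, which lay between 0.9906 and 1.0221 of the summed counts. The signal values were made by the authors as the mean of counts over median-of-ratios size factors in each group, which was checked by computing them again from the counts. The log2 fold changes of TBZ over control were made by the authors, and the p-value and adjusted p-value columns are theirs too, with no tool named in the sources used here. DESeq2 on the counts gave log2 fold changes within 0.001 of theirs for close to every gene (100% after rounding) and the same 222 calls. Identifiers were matched to GENCODE M21, where 54495 were found and 98.33% of these had the same start and end.

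The plan was limma on log2(FPKM + 0.5) unless read counts were in the table, and since they were, the gene test was the edgeR quasi-likelihood test on counts with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment over all tested genes. Adjusted p under 0.05 counted as changed. Of 31250 genes with a read, 18226 passed the filter, and the biological coefficient of variation was 8.3%. Errors of log2 fold changes are SE derived from the edgeR fit, as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. Values per group are mean and SD of TMM-scaled CPM. Intervals are at 95%. For single genes they come from the SE so derived. For medians of lists, and for differences between these, they come from resampling list members. Such intervals treat members as independent and do not measure the spread between libraries. The labels do not say that replicates are separate cultures from separate litters, so p-values measure the spread between these samples.

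A total of 29 gene lists with 641 symbols, of which 602 were tested, was compared with all other genes by camera (limma) with a preset correlation of 0.01, two-sided, adjusted over the 29 lists. Camera was repeated with an estimated correlation, and fry was run on the same lists. Single values per library were compared by two-sided exact permutation tests, whose smallest p is 0.1. The lists, the tests, the alternatives and the rule for naming genes were chosen before the data were examined. The rule named Slc18a2 and 11 lineage genes whatever their values. It also named the protein-coding genes with the largest rises and falls, up to 8 each way, among changed genes with non-overlapping groups and a mean FPKM of at least 1 in a group. From each called list it took the 3 members with the smallest p, and from other lists the 2 with the highest mean. Some genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen. Lists of general epithelium (24 genes), NRF2 targets (30), acinar genes outside the trypsin, elastase and amylase families (17) and stomach and oesophagus (37) were added after results were seen.

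The alternatives were DESeq2, RLE scaling, no filter, the replicate number as a block, limma on FPKM with other pseudocounts, filters, scalings, variance models and library weights, an added fold change threshold, and leaving out each library in turn. Thinning to the smallest library, a robust edgeR fit, list members in no other list, and the epithelial or stomach score as a covariate were added after the data were seen. For these covariates the score was the median over members of log2 CPM relative to the mean of each gene over all libraries. The scores printed per library are relative to the control mean instead. In 5 simulations with 18004 tested genes, the edgeR test recovered 30.4% of genes moved by 1.25-fold, 61.6% of those moved by 1.5-fold, 72% of those moved by 2-fold and 88.8% of those moved by 3-fold, of 250 each. Of 757 calls 75 (9.91%) were false, above the nominal 5%, and camera called 2 of 140 unmoved lists (1.43%). Genes were simulated independently of each other, so the share for camera does not carry over to lists with correlated members. In the data the estimated correlation reached 0.672, for sterol synthesis. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Strand, splicing and read-level alignment were not analysed here.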

Results

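Pancreatic buds were taken from mouse embryos at E12.5, when the epithelium holds multipotent progenitors and the first endocrine cells, and were kept in explant culture for 2 days. The medium held 10% fetal bovine serum and 0.1% DMSO. Control buds received the vehicle alone, and treated buds received 0.1 µM tetrabenazine (TBZ) for the whole culture. TBZ inhibits VMAT2, the product of Slc18a2, which loads dopamine, serotonin and other monoamines into vesicles. Poly-A RNA was sequenced from 3 control and 3 TBZ libraries, and the study asked how the VMAT2-monoamine pathway acts on the developing pancreas. The libraries held 46976677, 50620936 and 41005819 counted reads in control replicates 1 to 3, and 40840929, 40973254 and 35825033 in TBZ replicates 1 to 3. The controls were the deeper group, at 46.2 ± 4.85 megareads against 39.2 ± 2.94 megareads (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest p that 3 against 3 libraries can give).

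All 6 libraries were close to each other, with Pearson correlations of log2 CPM from 0.9875 to 0.994. The lowest value was between control replicate 3 and TBZ replicate 3. The first principal component carried 34.4% of the variance and set control replicate 3 (-34.5) apart from TBZ replicates 1 and 3 (22.3 and 23.3), with the other libraries between -4.93 and -2.20. Several genes of stomach and oesophagus tissue, which lies beside the pancreatic bud, were high in control replicate 3 or low in TBZ replicates 1 and 3, and their relation to this component was not tested. Pitx1, a transcription factor of the caudal foregut among other tissues, stood at 47.8 CPM in control replicate 3, at 5.93 and 6.73 CPM in the other controls, and at 1.51, 7.24 and 1.29 CPM in TBZ replicates 1 to 3. Sox2, a foregut transcription factor, stood at 12.7 CPM in control replicate 3 and at 0.420 to 2.35 CPM elsewhere. Barx1, a transcription factor of stomach mesenchyme, stood at 68.5 and 74.6 CPM in TBZ replicates 1 and 3 and at 93.7 to 109 CPM in the other libraries. Over 25 tested genes of a stomach and oesophagus list made after these values were seen, 21 had a negative log2 fold change in TBZ, the median was -0.32 and none passed the edgeR gene test, against 1 higher with DESeq2 and 1 higher and 11 lower with no filter in edgeR. The score of that list (the median member on the log2 scale, relative to the control mean of each gene) was 0.01, -0.58 and 0.34 in the controls and -1.20, 0.07 and -1.03 in TBZ replicates 1 to 3 (two-sided exact permutation p = 0.3).

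Digestive enzyme genes were the largest named group among the genes that rose in TBZ buds, and the genes that fell included enzymes of antioxidant defence and of cholesterol synthesis. Try10, a trypsinogen gene, rose from 4.21 ± 0.428 to 10.3 ± 0.223 CPM (SD, n = 3 each), 2.46-fold with an SE of 0.11 on the log2 scale and an edgeR adjusted p of 0.00333. Pnliprp1, a pancreatic lipase-related gene, rose from 929 ± 84.0 to 1730.2 ± 123 CPM (SD, n = 3 each), a log2 fold change of 0.90 ± 0.07 (SE) with an edgeR adjusted p of 0.00333. Srxn1, which encodes the sulfiredoxin that restores oxidised peroxiredoxins, fell from 67.4 ± 3.49 to 39.6 ± 2.18 CPM (SD, n = 3 each), a log2 fold change of -0.77 ± 0.06 (SE) with an edgeR adjusted p of 0.00333. Nqo1, a quinone reductase, had the largest fall of the 6 genes that went down, with a log2 fold change of -1.06 ± 0.12 (SE).

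In all, 34 of 18226 tested genes changed at an edgeR quasi-likelihood adjusted p under 0.05, of which 28 rose and 6 fell. At an unadjusted p under 0.05 there were 1752 genes, 925 of them higher in TBZ. Each of the 34 genes had TBZ and control values that did not overlap, as did 2824 (15.5%) of all tested genes, where chance gives 10%. Among protein-coding genes with a mean FPKM of at least 1 in a group, which leaves out Fmo4 (log2 1.17) and Amy2b (1.10), the next rises in size were those of the elastase gene Cela3b (log2 1.23), the trypsinogen genes Prss3 (1.07), Gm10334 (1.04) and Try5 (0.90), the linker histone gene Hist1h1c (0.93) and the flavin monooxygenase gene Fmo2 (0.86). The other falls were those of the metallothionein gene Mt1 (log2 -0.78), of Gclc (-0.42), whose product catalyses the rate-limiting step of glutathione synthesis, and of Msmo1 and Hsd17b7 (both -0.31), which act in cholesterol synthesis. Try5, Try10, Prss3 and Gm10334 lie in the trypsinogen cluster on chromosome 6 between positions 41311233 and 41446145 (mm10). Reads of such near-identical copies can be assigned to the wrong member, so their single values are uncertain, and the same holds for Hist1h1c within its histone family. The authors' deposited table lists 222 changed genes, 170 higher and 52 lower, which include all 34 with the same sign. Whichever library was left out, Pnliprp1, Srxn1, Nqo1, Hist1h1c and Try10 passed, while Bhlha15 and Mt1 passed in 5 of the 6 fits, Cpa1 and Fmo2 in 3, Cela3b, Egr1, Gclc and Try5 in 2, Hsd17b7, Msmo1 and Prss3 in 1 and Gm10334 in 0. The count of genes was 13 without control replicate 2, 11 without TBZ replicate 1 and 5 without TBZ replicate 3. It was 222 with DESeq2, 445 with no expression filter, 14 with limma on FPKM, 1 with the stomach score as a covariate and 0 with the score of general epithelial genes as a covariate.

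**Figure D1:**
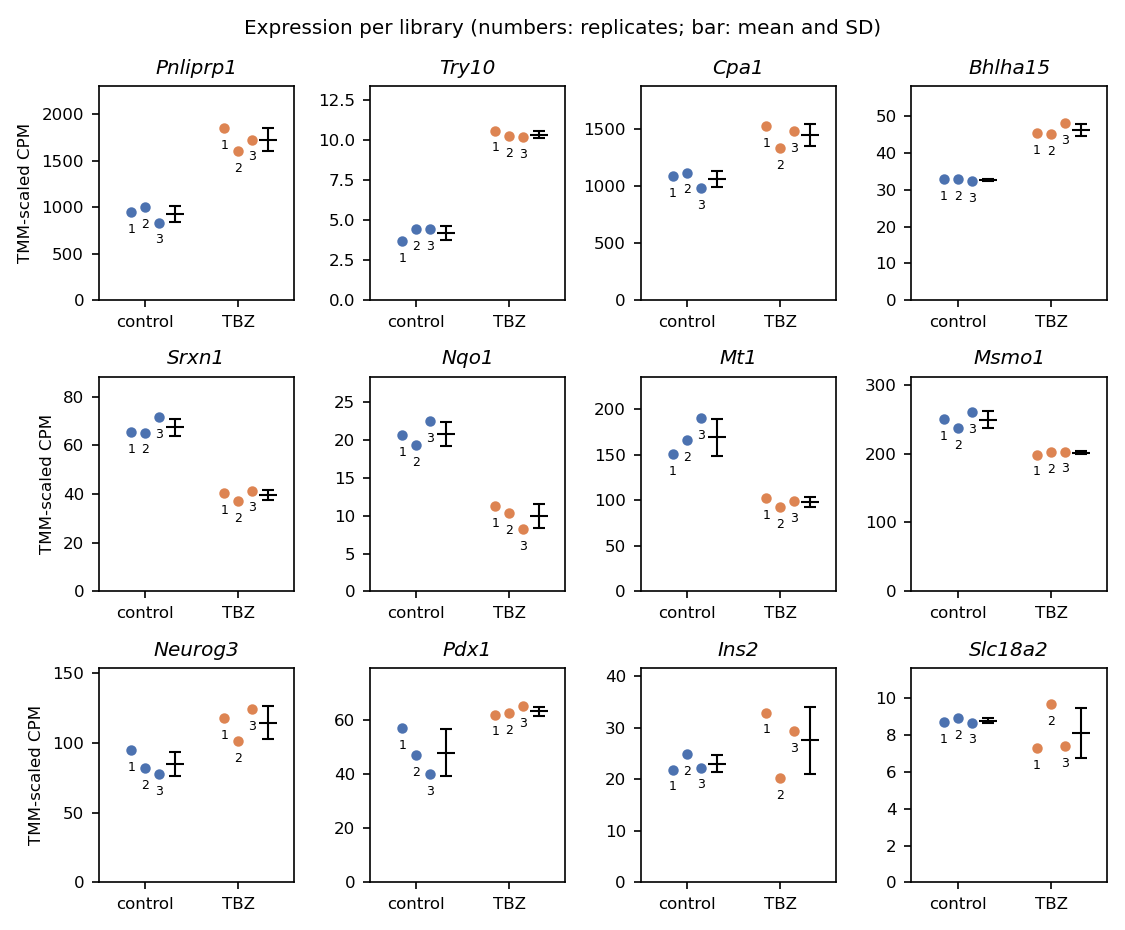
Expression of 12 genes in each library, as TMM-scaled CPM on an axis that starts at 0; points are libraries, numbers are replicates, and the bar gives the mean and SD of each group (n = 3). Pnliprp1, Try10, Cpa1 and Bhlha15 were higher in all 3 TBZ libraries, Srxn1, Nqo1, Mt1 and Msmo1 were lower in all 3, and Ins2 and Slc18a2 overlapped between the groups.

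Genes of acinar cells, which make the digestive enzymes, were higher in every TBZ library. Of 29 tested members of the acinar list, 28 had a positive log2 fold change, 11 rose past the threshold, 18 did not pass and none fell; the median was 0.65 (edgeR). Adjusted over the list alone, 22 rose. Over all genes DESeq2 put 16 members higher, edgeR with no filter 20 and limma on FPKM 4. Besides Prss3, Try5 and Cela3b, the members that rose included Cpa1, a carboxypeptidase gene (log2 0.44 ± 0.06 SE, edgeR adjusted p = 0.0316), and Cel (0.69), the bile-salt-dependent lipase. Bhlha15, a transcription factor of mature secretory cells also called Mist1, rose from 32.6 ± 0.332 to 46.2 ± 1.65 CPM (log2 0.50 ± 0.05 SE, edgeR adjusted p = 0.00632). Ptf1a, the transcription factor that specifies acinar cells, had a log2 fold change of 0.15 ± 0.11 (SE) and an edgeR adjusted p of 0.711. Amy2b is in the list through a gene model that the deposited annotation calls an unprocessed pseudogene, so its log2 fold change of 1.10 is uncertain.

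The acinar list took 0.645 ± 0.0519% of all counts in control and 0.971 ± 0.0908% in TBZ libraries (SD, n = 3 each; two-sided exact permutation p = 0.1). Its score was 0.79, 0.47 and 0.69 in TBZ replicates 1 to 3 and between -0.14 and 0.10 in the controls. Against all other genes the acinar list was higher by camera with a preset correlation of 0.01 (adjusted p = 7.50e-69), and the call was lost at adjusted p = 0.0951 with an estimated correlation. Beside this group, 22 of 24 general epithelial genes had a positive log2 fold change, with a median of 0.15 and none past the edgeR threshold (3 higher with DESeq2), and the stomach score was lower in TBZ replicates 1 and 3.

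Genes of pancreatic progenitors lay higher in TBZ, by a smaller amount than the acinar genes. Of 20 tested members, 19 had a positive log2 fold change and 1 rose past the threshold, Cpa1, which marks multipotent tip progenitors as well as acinar cells; 10 rose when adjusted over the list alone, and the median was 0.23 (edgeR). The duodenal and pancreatic transcription factor Pdx1 went from 47.8 ± 8.56 to 63.0 ± 1.63 CPM (SD, n = 3 each; log2 0.40 ± 0.11 SE, edgeR adjusted p = 0.249). Nkx6-1 (log2 0.46), Nkx2-2 (0.45) and Sox9 (0.23) had non-overlapping groups and did not pass with edgeR (adjusted p = 0.0943, 0.124 and 0.237). DESeq2 put 6 members higher past the threshold, and the authors' deposited table has Nkx6-1, Nkx2-2 and Pdx1 past it (adjusted p = 2.47e-05, 0.000333 and 0.0157) and Sox9 not (0.0587). Foxa1 was the exception at -1.67 ± 1.00 (SE), with 0.248 and 0.112 CPM in TBZ replicates 1 and 3 and 3.59 to 16.0 CPM elsewhere. Of the 20 members 7 stand in another list too, among them Cpa1 (acinar), Nkx6-1 (beta cell) and Nkx2-2 (endocrine progenitor). The camera call for the progenitor list (adjusted p = 4.85e-16) was lost with an estimated correlation (adjusted p = 0.119). Beside this group 22 of 24 general epithelial genes had a positive log2 fold change (median 0.15), and the stomach score was lower in TBZ replicates 1 and 3. The median of the progenitor list was 0.15 with the epithelial score and 0.25 with the stomach score as a covariate, called in both.

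Genes of endocrine progenitors and endocrine cells were higher on balance, while no member and no hormone gene passed the edgeR gene test. In the endocrine progenitor list 26 of 28 members had a positive log2 fold change, with a median of 0.24, and 7 rose when adjusted over the list alone (edgeR). Neurog3, the factor that commits progenitors to the endocrine lineage, stood at 84.8 ± 8.87 CPM in control and 114 ± 11.7 CPM in TBZ (SD, n = 3 each; log2 0.43 ± 0.09 SE, edgeR adjusted p = 0.124), and Cbfa2t3 had a log2 fold change of 0.40 (edgeR adjusted p = 0.0794). Both passed with DESeq2, which put 4 members of the list higher, and in the deposited table (adjusted p = 0.000332 and 0.000443). The log2 fold changes of the hormone genes were 0.24 for Ins1, 0.26 for Ins2, 0.23 for Gcg, 0.12 for Sst, -0.25 for Ppy and 0.41 for Ghrl, with edgeR adjusted p-values from 0.534 to 0.908. With the stomach score as a covariate the direction reversed for Ins1 (-0.02), Ins2 (-0.08), Gcg (-0.39) and Sst (-0.23), while Ppy and Ghrl kept theirs. Gcg was at -0.03 without TBZ replicate 1, and Sst at -0.05 without control replicate 1 and -0.04 without TBZ replicate 3. For Ins2 the 95% interval of the log2 fold change ran from -0.08 to 0.60. The annotated span of Ins2 on chromosome 7 runs from position 142678656 to 142743381 (mm10), and reads of other transcripts within it may be counted to the gene.

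Among lists of differentiated endocrine cells, 22 of 26 pan-endocrine secretory genes (median 0.13), 17 of 22 beta cell genes (0.20) and 13 of 15 alpha cell genes (0.16) had positive log2 fold changes. The members with the smallest p included the prohormone convertase gene Pcsk1 (log2 0.36), Cplx2 (0.17) and Chga (0.30) among secretory genes, Ero1lb (0.36) and the potassium channel gene Kcnj11 (0.37) in beta cells, and Pou3f4 (0.39) and Etv1 (-0.15) in alpha cells. Of these, Ero1lb and Kcnj11 passed with DESeq2 and in the deposited table (adjusted p = 0.0101 and 0.0192). Of 11 delta, PP and epsilon cell genes, 5 were above and 6 below 0, among them Pyy at 0.05 and Rbp4 at 0.23, and that list was not called (camera adjusted p = 0.708). Camera with the preset correlation called the endocrine progenitor (adjusted p = 3.85e-13), pan-endocrine (0.000782), beta (7.57e-05) and alpha cell (0.0269) lists. With an estimated correlation the adjusted p was 0.430, 0.705, 0.430 and 0.724 in the same order. These lists did not separate TBZ replicate 2 from the controls: its scores were 0.04, -0.04, -0.01 and -0.09 in that order, each within the range of the control scores. TBZ replicate 2 was also the TBZ library whose stomach score was close to control, and general epithelial genes had a median of 0.15. With the stomach score as a covariate the median was 0.10 for endocrine progenitors, still called, and -0.04, -0.02 and -0.17 for the other lists; the pan-endocrine and beta calls ended, and the alpha list was called in the opposite direction. The pan-endocrine call also ended without TBZ replicate 3 (median 0.08, camera adjusted p = 0.0673), and the alpha call without control replicate 3 (median 0.05, adjusted p = 0.789), TBZ replicate 1 (0.05, 0.227) or TBZ replicate 3 (0.08, 0.387). Both ended with the epithelial score as a covariate (0.0666 and 0.119), and the alpha call with limma on FPKM with no variance trend (0.0584) or with library weights (0.195).

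**Figure D2:**
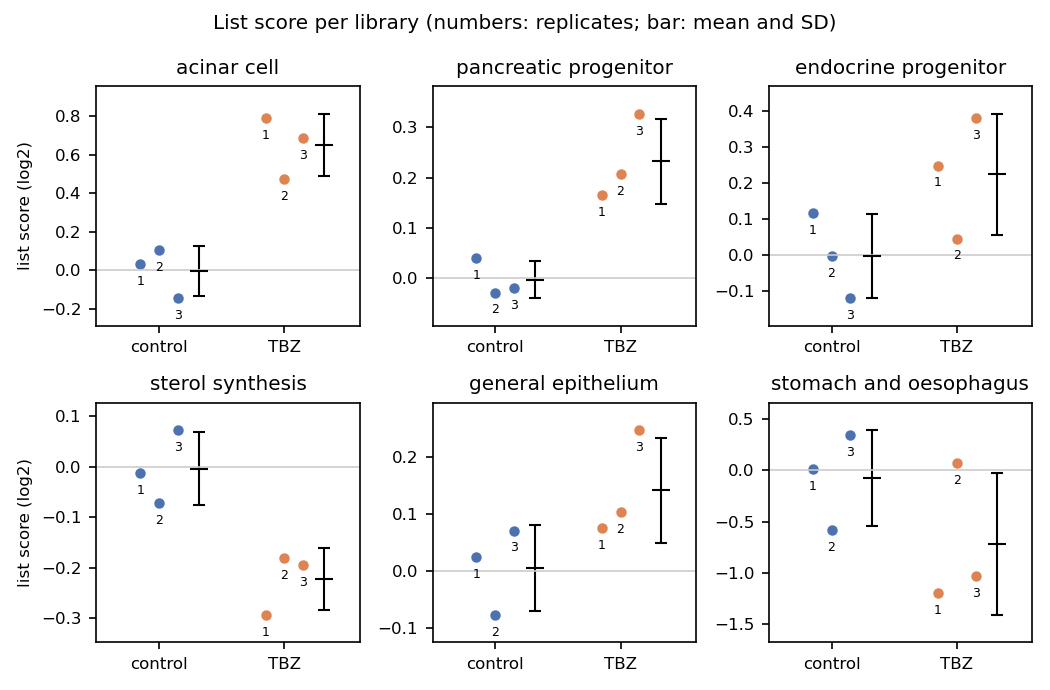
List scores in each library: the median over members of log2 CPM relative to the control mean of each gene, for 4 lists fixed beforehand and for the general epithelium and stomach lists added later; points are libraries, numbers are replicates, and bars give the mean and SD (n = 3). Acinar scores were 0.47 to 0.79 in TBZ and -0.14 to 0.10 in control, while TBZ replicate 2 lay among the controls for endocrine progenitors (0.04) and for stomach genes (0.07).

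Ductal and trunk epithelial genes went in both directions. Of 26 tested members 16 were above 0 and 10 below, none passed over all genes and 8 rose when adjusted over the list alone (edgeR). Bicc1 (log2 0.28 ± 0.05 SE), Cdh1, which encodes E-cadherin (0.27 ± 0.05), and Muc1 (0.30 ± 0.06) had the smallest p-values, with edgeR adjusted p of 0.0558, 0.0759 and 0.101. These 3 passed with DESeq2, which put 4 members higher, and in the deposited table (adjusted p = 0.000169, 0.000218 and 0.00325). The median was 0.08 and the mean -0.01, so that the 2 differ in sign, and camera called the list higher (adjusted p = 0.000502; adjusted p = 0.430 with an estimated correlation). The call ended with the epithelial score as a covariate (adjusted p = 0.976). That score shares Epcam, Cdh1, Krt8 and Krt18 with the ductal list, so the loss of the call is partly built in.

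Signalling lists shifted by small amounts. Of 20 Notch pathway genes, 16 were above 0 (median 0.07), none passed over all genes and 2 did over the list alone (edgeR). These were the modifier gene Lfng (log2 0.24) and the target gene Heyl (0.26), followed by the target gene Nrarp (0.26). The Notch list was called higher by camera (adjusted p = 0.000502; adjusted p = 0.273 with an estimated correlation). General epithelial genes had a larger median beside it (0.15, 22 of 24 above 0), and the stomach list a median of -0.32. Of 26 cAMP response and immediate-early genes, 19 were above 0 (median 0.08), and the immediate-early transcription factor gene Egr1 rose from 86.5 ± 4.05 to 119 ± 8.54 CPM (log2 0.45 ± 0.06 SE, edgeR adjusted p = 0.0292). Ier2 had a log2 fold change of 0.16 and Sik1, a known target of cAMP signalling, of -0.21. Adjusted over the list alone 3 genes rose and 1 fell, and camera called the list higher (adjusted p = 0.00413; adjusted p = 0.430 with an estimated correlation). The call ended without TBZ replicate 1 (adjusted p = 0.178) and with the stomach score as a covariate (0.170). Of 16 TGF-beta target and matrix genes, 12 were above 0 (median 0.10), among them Smad7 (log2 0.28) and Cyr61 (0.36), and none passed with edgeR. Cyr61 passed with DESeq2 and in the deposited table (adjusted p = 0.0282). That list was called higher (camera adjusted p = 0.00775; adjusted p = 0.724 with an estimated correlation) and lost the call without control replicate 3 (median 0.03, adjusted p = 0.239) and without TBZ replicate 1, where the median turned to -0.02 (adjusted p = 0.663). With the stomach score as a covariate its median was -0.06 (adjusted p = 0.434), and 9 fits with limma on FPKM ended the call too (0.0534 to 0.228), so that it held in 14 of 26 alternatives besides the other set tests.

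Sterol synthesis genes were lower in TBZ as a group. All 22 tested members had a negative log2 fold change, with a median of -0.23; 2 fell past the threshold over all genes and 18 over the list alone (edgeR). Msmo1, the sterol C4-methyl oxidase, fell from 249 ± 12.0 to 201 ± 2.37 CPM (log2 -0.31 ± 0.05 SE, edgeR adjusted p = 0.0395), and Hsd17b7 fell from 65.8 ± 1.48 to 53.1 ± 0.729 CPM (log2 -0.31 ± 0.04 SE, adjusted p = 0.0292; SD, n = 3 each). Cyp51, the sterol 14-demethylase, had a log2 fold change of -0.27 (edgeR adjusted p = 0.0753) and passed in the deposited table (adjusted p = 0.000239) and with DESeq2, which put 11 members lower. Camera called the list lower (adjusted p = 5.40e-26), and with an estimated correlation the adjusted p was 0.273. The general epithelial median of 0.15 and the stomach median of -0.32 stood beside this fall too.

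The retinoic acid, mesothelium and Wnt target lists were also lower by camera, and no member of these lists passed the gene test with edgeR or DESeq2. With no filter in edgeR Rarb, Rspo1, Krt19, Rnf43 and Tnfrsf19 passed. Of 15 retinoic acid pathway genes 13 were below 0 (median -0.20), including the synthesis gene Aldh1a1 (log2 -0.33), the receptor gene Rarb (-0.57) and the degradation gene Cyp26b1 (-0.18); camera gave an adjusted p of 0.000171, and 0.430 with an estimated correlation. Of 11 mesothelial genes 10 were below 0 (median -0.19), including Rspo1 (log2 -0.67), Bnc1 (-0.24) and Krt19 (-0.51), which is also a ductal keratin; camera gave an adjusted p of 0.000782, and 0.614 with an estimated correlation. Krt19 stood at 62.7 ± 28.6 CPM in control (SD, n = 3), a spread wider than its difference from the 43.8 ± 3.35 CPM of TBZ. Of 14 Wnt targets 10 were below 0 (median -0.13), including the receptor ligase genes Znrf3 (log2 -0.18) and Rnf43 (-0.44) and the receptor gene Tnfrsf19 (-0.23); camera gave an adjusted p of 0.0269, and 0.705 with an estimated correlation. The stomach score fell beside these lists in TBZ replicates 1 and 3, and with it as a covariate none of the 3 was called (adjusted p = 0.618, 0.375 and 0.836 in the order given). Without control replicate 3 the mesothelium (adjusted p = 0.0618) and Wnt (0.424) calls ended, the Wnt median turning to 0.01, and the Wnt call also ended without TBZ replicate 1 (0.146) and TBZ replicate 3 (0.105). It ended in 5 fits with limma on FPKM as well: with no filter (0.0625), a filter at 1 (0.0742), quantile scaling (0.0682), scaling to the library sum (0.0673) and library weights (0.173).

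**Figure D3:**
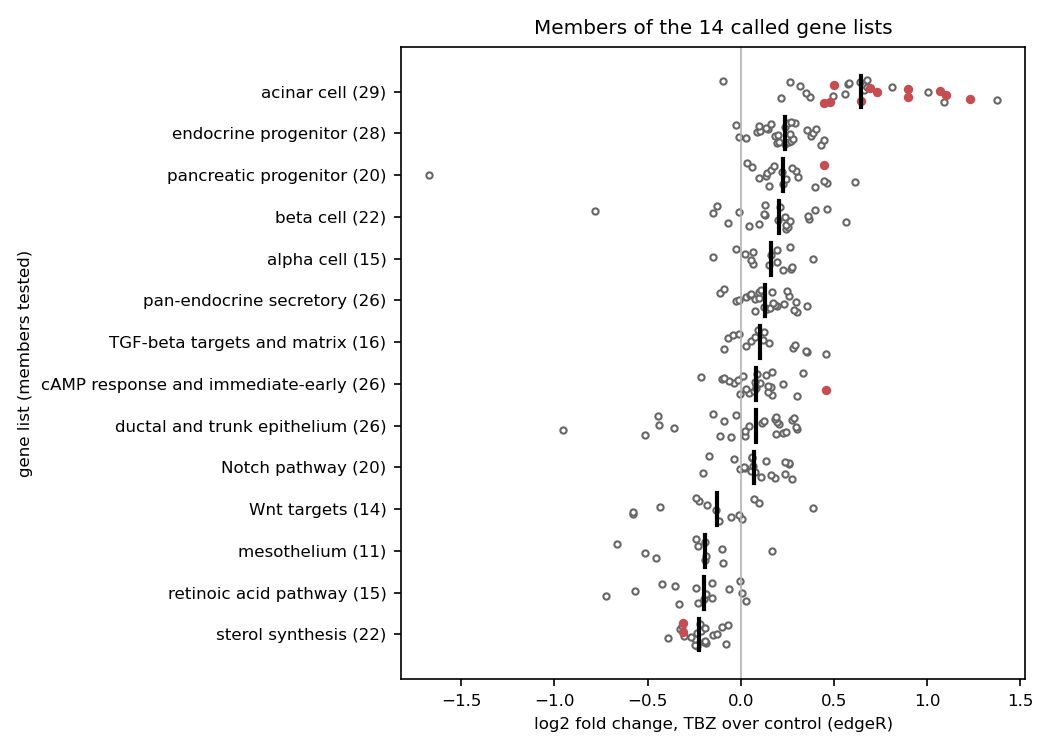
Log2 fold change in TBZ over control (horizontal axis, edgeR) of each tested member of the 14 called lists (vertical axis, number of members in brackets); filled red points passed the adjusted p threshold over all genes, open points did not, and the black bar is the list's median. Acinar genes had a median of 0.65 and sterol synthesis genes of -0.23, and the lists between them had medians from -0.20 to 0.24.

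The target of the drug and the monoamine genes did not pass the gene test. Slc18a2 (ENSMUSG00000025094, chromosome 19, positions 59260878 to 59296012 in mm10) stood at 8.78 ± 0.132 CPM in control and 8.13 ± 1.35 CPM in TBZ (SD, n = 3 each). Its log2 fold change was -0.11, with a 95% interval from -0.38 to 0.16 and an edgeR adjusted p of 0.814. Of 14 tested genes of monoamine synthesis, transport and breakdown, 6 were above and 8 below 0. Ddc, the decarboxylase that forms dopamine and serotonin, had a log2 fold change of 0.21 (edgeR adjusted p = 0.325). Adjusted over the list alone, 2 members were higher and 1 lower. The tryptophan hydroxylase genes Tph1 and Tph2 and the dopamine transporter gene Slc6a3 had 47, 22 and 8 reads over all 6 libraries and were too low to be tested. Of 16 tested monoamine receptor genes 12 were above 0, including Adra2a (log2 0.21) and Htr1b (0.13), and the dopamine receptor genes Drd1 and Drd2 had 1 and 17 reads in total. Neither list was called (camera adjusted p = 0.654 and 0.308), and for the first the median (-0.01) and the mean (0.01) differ in sign.

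Apart from mesothelium, which was called lower, lists of other cell types in the explant were not called. Mesenchymal genes, 14 above and 16 below 0 (camera adjusted p = 0.653), held the abundant collagen genes Col3a1 at log2 -0.03 and Col1a1 at 0.08. Of 20 endothelial genes 16 were above 0 (adjusted p = 0.0737), with Cdh5 at 0.05 and Ets1 at 0.01, the latter below 0 with quantile scaling and with scaling to the library sum. Of 22 blood and macrophage genes 16 were below 0 (adjusted p = 0.0805), with the embryonic globin gene Hbb-y at -0.21 and Lyz2 at -0.10. Of 23 neural crest, glial and neuronal genes 17 were below 0 (adjusted p = 0.233), with Erbb3 at 0.26 and Hand2 at 0.02. The list of neighbouring gut, spleen and liver, fixed beforehand and with 13 tested members, had 7 above 0 (adjusted p = 0.708), with the spleen gene Tlx1 at 0.01 (below 0 with scaling to the library sum) and Nkx2-5 at 0.08, and its median of 0.01 and mean of -0.13 differ in sign. Adjusted over the list alone 1 of its members was higher, Tff2 (log2 1.37), and 1 lower, Sox2 (-2.62), both named after their values were seen.

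Proliferation, stress and energy genes were not called either. Of 30 cell cycle genes 13 were above and 17 below 0 (camera adjusted p = 0.653), with the proliferation genes Top2a at log2 0.06 and Mki67 at 0.17. Hypoxia and glycolysis genes (8 of 23 above 0, adjusted p = 0.584) held Pkm at -0.02 and Eno1 at -0.01, and adjusted over the list alone 1 member was higher, Vegfa (0.22), and 1 lower, Gapdh (-3.11). Gapdh, named with Vegfa after the values were seen, stood at 34.5 ± 28.5 CPM in control and 4.01 ± 0.312 CPM in TBZ (SD, n = 3 each), with groups that overlap, an edgeR adjusted p of 0.190 and pseudogene copies that make its reads uncertain. The median of that list was -0.01 and the mean -0.14. Genes of the unfolded protein and integrated stress response (12 of 23 above 0, adjusted p = 0.708) held the chaperone genes Hspa5 at 0.04 and Calr at -0.00, with a median of 0.01 and a mean of -0.01. Respiratory chain genes (17 of 24 above 0, adjusted p = 0.655) held Atp5b at 0.03 and Atp5a1 at 0.01, both below 0 with quantile scaling. Interferon genes (9 of 20 above 0, adjusted p = 0.242) held Stat2 at -0.30 and Bst2 at -0.04, and p53 and apoptosis genes (6 of 18 above 0, adjusted p = 0.392) held Plk2 at 0.19 and Ccng1 at -0.13, with 2 higher and 2 lower over the list alone. Hedgehog and FGF pathway genes (9 of 22 above 0, adjusted p = 0.242) held Smo at -0.03 and Fgfr1 at -0.02, with 1 higher and 2 lower over the list alone, a median of -0.03 and a mean of -0.34. None of the members of these 7 lists passed the edgeR test over all genes. With DESeq2 1 p53 and apoptosis gene was higher, Plk2 (adjusted p = 0.0157 in the deposited table), and 1 Hedgehog and FGF pathway gene was higher and 1 lower.

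Over all lists, camera with the preset correlation called 14 of 29, 10 higher and 4 lower. None was called with an estimated correlation, where 4 of the 14 had an unadjusted p under 0.05 (acinar, pancreatic progenitor, Notch and sterol synthesis), and none was called by fry.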

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

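The thinned, robust, unique-member, epithelial and stomach settings were chosen after results were seen. The genes changed by TBZ (34) numbered 222 with DESeq2, 445 with no filter in edgeR (263 higher, 182 lower), 5 with the replicate number as a block, 14 with limma on FPKM, 13 and 14 with pseudocounts of 0.1 and 1, 0 with no filter (2135 at an unadjusted p under 0.05), 16 with a filter at 1, 14 with median-of-ratios scaling, 9 with quantile scaling, 12 with scaling to the library sum, 1 with no variance trend (Try10), 11 with robust limma and 18 with library weights. They numbered 7 with an absolute log2 fold change of at least 1 in edgeR, 6 higher and 1 lower. The DESeq2 and unfiltered edgeR sets held all 34. The count was 34 with RLE factors and 39 with thinning, both holding all 34 genes, and 50 with robust edgeR, which shared 29 of the 34. It ran from 5 without TBZ replicate 3 to 36 without control replicate 3, with 11 without TBZ replicate 1 and 13 without control replicate 2. It was 0 with the epithelial covariate (edgeR, 1506 at an unadjusted p under 0.05) and 1 with the stomach covariate (Pnliprp1, 1165 at an unadjusted p under 0.05). The acinar median was 0.869 with the epithelial score and 0.472 with the stomach score. The cause of these differences was not tested.

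The replicate block, a paired fit, called Pnliprp1, Srxn1, Hist1h1c, Gm12966 and Try10, and 15 lists. The labels do not say whether the numbers pair the samples, and 6 libraries are too few to settle it. Deviations from the group mean correlated at 0.00174, -0.153 and -0.0766 for equal numbers, and not every library was closest to the library of its own number.

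Of 14 called lists, 0 were called with an estimated correlation (4 at an unadjusted p under 0.05) and 0 by fry (4 at an unadjusted p under 0.05), where medians stay as they are. For these tests the adjusted p was 0.119 and 0.0730 for pancreatic progenitors (median 0.2255), 0.430 and 0.314 for endocrine progenitors (0.2367), 0.0951 and 0.0718 for acinar genes (0.6456) and 0.273 and 0.128 for sterol synthesis (-0.2259). In the 26 other alternatives these 4 lists and Notch were called each time. The other lists were called in 14 (TGF-beta) to 25 (beta, ductal, retinoic acid) of 26. The count was 11 without control replicate 3 and 16 without control replicate 2. With the stomach covariate 12 lists were called, 7 of them among the 14, and the test reversed for the pan-endocrine (-0.03845), alpha (-0.1697), mesothelium (0.04179), Wnt (0.03517) and TGF-beta (-0.05823) lists. The alpha list is among these 7, called lower instead of higher (camera adjusted p = 0.00368). The lowest Spearman correlation was 0.99217, for the same pair as Pearson's.

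For 18 changed named genes, 225 of 450 alternative fits kept the call, 225 lost it and 0 reversed. For the 73 others, 46 of 1825 fits passed the threshold and 52 reversed, in 24 genes. Log2 values with the stomach covariate were 0.03579 for Slc18a2, -0.02274 for Ins1, -0.08062 for Ins2, -0.3891 for Gcg, -0.2335 for Sst, -0.1837 for Pyy, -0.05704 for Rbp4, -0.06456 for Col1a1, 0.03507 for Krt19, -0.02407 for Ets1, -0.02092 for Hand2, 0.07066 for Pkm, 0.07433 for Eno1, -0.06842 for Hspa5 and 0.01222 for Smo. With the epithelial covariate they were 0.08545 for Col3a1, 0.2084 for Lyz2, 0.05095 for Calr, 0.00459 for Smo and 0.03786 for Fgfr1. Quantile scaling gave -0.005595 for Ets1, -0.003289 for Atp5b and -0.01102 for Atp5a1, and scaling to the library sum gave -0.008463 for Ets1, -0.009004 for Tlx1 and -0.006632 for Atp5a1. Library weights gave -0.006232 for Ets1, -0.007938 for Tlx1, 0.01522 for Pkm, 0.0447 for Eno1 and -0.009804 for Hspa5. With 1 library left out in turn the values ran from -0.02743 to 0.4725 for Gcg, -0.05429 to 0.3321 for Sst, -0.05082 to 0.1723 for Pyy, -0.08667 to 0.04334 for Col3a1, -0.02439 to 0.1393 for Col1a1, -0.04125 to 0.06746 for Ets1, -0.01293 to 0.04468 for Hand2, -0.2578 to 0.02308 for Lyz2, -0.04265 to 0.08693 for Tlx1, -0.02336 to 0.1365 for Nkx2-5, -0.0593 to 0.04685 for Pkm, -0.06157 to 0.08427 for Eno1, -0.05588 to 0.04649 for Calr, -0.01684 to 0.1275 for Hspa5 and -0.1028 to 0.03067 for Bst2. The cause of these reversals was not tested.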

Other observations

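The tests of acinar genes against epithelium, gene families and stomach tissue, of progenitor genes against epithelium, and of pancreatic progenitors against stomach tissue were chosen only after the results were seen. So were all genes named here that earlier comparisons leave out. Among other genes that rose in TBZ were Gamt (log2 0.42 ± 0.05 SE), the methyltransferase that forms creatine, Cbs (0.42 ± 0.06), which acts in transsulfuration, the glutamine transporter gene Slc38a3 (0.41 ± 0.05), the mitochondrial malic enzyme gene Me3 (0.81 ± 0.11) and Txnip (0.40 ± 0.06), an inhibitor of thioredoxin, with edgeR adjusted p-values of 0.0204, 0.0316, 0.0270, 0.0340 and 0.0389. The flavin monooxygenase gene Fmo4 rose as Fmo2 did (1.17 ± 0.16 and 0.86 ± 0.11), and Fmo1 had a log2 fold change of 0.58 without passing (edgeR adjusted p = 0.197). Camp, a granule gene of neutrophils, had a log2 fold change of 1.27 and did not pass (edgeR adjusted p = 0.0627).

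Genes activated by NRF2, the transcription factor of the oxidative stress response, were lower in TBZ. Of 30 listed targets 28 had a negative log2 fold change, and the median was -0.20. With edgeR 3 fell past the threshold (Nqo1, Srxn1 and Gclc), with Cbr3 (-1.17) and Pir (-0.79) not passing. DESeq2 put 10 targets lower, edgeR with no filter 12 and limma on FPKM 2. The list score was lower in all 3 TBZ libraries (two-sided exact permutation p = 0.1), and camera gave an unadjusted p of 9.05e-38 with the preset and 0.0133 with an estimated correlation. As 10 of the targets had been seen before, the test used the other 20. Of these 18 were lower, the median was -0.1722 (95% interval -0.1953 to -0.1319), and camera gave an unadjusted p of 3.79e-12 with the preset and 0.0479 with an estimated correlation. The trend of log2 fold changes on GC content and gene length was small over all genes (95% of fitted values from -0.04 to 0.04) and at most 0.02 in size for these 20 targets, which argues against it as the whole cause. Its removal moved little and left a median of -0.1662 (-0.1878 to -0.1253). Beside these genes the median was 0.15 for general epithelial genes (22 of 24 above 0) and -0.32 for stomach genes. Lower activity of this pathway in TBZ buds may explain the values, as a hypothesis, and a different mix of cells was not tested for these genes.

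For the rise of acinar genes, some explanations have values against them as the whole cause. A part played by the mix of stomach and pancreatic tissue stays open. The intervals below resample list members and leave out the spread between libraries. The acinar median exceeded that of general epithelial genes by 0.4945 (95% interval 0.3465 to 0.6044) on the log2 scale. A larger share of epithelium of the same make-up would move both alike. Less stomach epithelium with more pancreatic epithelium need not do so, and the gap does not bear on that mix. The acinar median also exceeded that of progenitor and endocrine progenitor genes by 0.4284 (0.3066 to 0.5578). This gap cannot decide on stomach tissue, since the lists did not move alike with the stomach score as a covariate. The median went from 0.6456 to 0.472 for acinar genes and from 0.2367 to 0.0975 for endocrine progenitors. For pancreatic progenitors it went from 0.2255 to 0.2545. The trend on GC content and length reached at most 0.03 in size for acinar genes, far under their median, which was 0.661 (0.5049 to 0.7561) after its removal. Over 14 genes outside the trypsin, elastase and amylase families the median was 0.489 (0.3159 to 0.6791). Of these 7 had been seen before, and the other 7, of which 6 were higher, had a median of 0.3159 (0.2162 to 0.5834). All 14 stand in the acinar list already called, so the other 7 are not a separate test of the rise. More acinar cells, or more enzyme transcripts per acinar cell, may underlie the rise, and bulk RNA does not separate these.

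For progenitor and endocrine progenitor genes the tissue mix stays open. Their joint median exceeded that of general epithelial genes by 0.07689, with a 95% interval that holds 0 (-0.01559 to 0.1574), so a larger share of epithelium in TBZ explants may account for it. For endocrine progenitors, less stomach tissue in TBZ replicates 1 and 3 also stays open: 12 stomach and oesophagus markers not looked at before had a median of -0.1486 (-0.423 to -0.0756), with 10 of 12 lower. Pancreatic progenitors kept a median of 0.2545 (0.1139 to 0.2996) with the stomach score as a covariate. This fit cannot decide on that tissue, since the score was low in TBZ replicates 1 and 3 and so overlaps with the treatment. The interval also leaves out the spread between libraries, and Foxa1 stands in both the stomach and the progenitor list. The trend on GC content and length reached at most 0.04 in size for these genes, which argues against it as the whole cause, and its removal moved little (median 0.2283, 0.175 to 0.267), and a direct effect of TBZ on these cells stays untested.

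The stomach and oesophagus list holds 37 genes, of which 25 were tested, 18 had been seen before and 8 stand in lists fixed earlier. Camera gave an unadjusted p of 2.05e-05 with the preset and 0.186 with an estimated correlation. Of the 25 genes, 12 were highest in control replicate 3, and 13 were lower in both TBZ replicates 1 and 3 than in every other library. The stomach enzyme gene Cym stood at 63.4 CPM in control replicate 3, at 12.7 and 15.5 CPM in the other controls, and at 1.54, 28.5 and 2.78 CPM in TBZ replicates 1 to 3. Tff2 went the other way, with a log2 fold change of 1.37 (edgeR adjusted p = 0.185). For general epithelial genes camera gave an unadjusted p of 7.76e-11 with the preset and 0.136 with an estimated correlation, and for the acinar genes outside the 3 enzyme families 1.75e-37 and 0.00227. Sterol synthesis genes had a median of -0.2194 after the trend on GC content and length was removed and of -0.2287 with every library thinned.

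The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As many genes as the real 34 came from 1 of the 10 splits, the real one, and the highest other count was 1. As many lists as the real 14 came from 4 of the 10, the real one included, and the highest other count was 19. Of the 14 called lists, 5 had their smallest p in the real split (acinar, pancreatic progenitor, sterol synthesis, Notch and cAMP), and 9 had another split with a p as small. Camera with the preset correlation also called the acinar list in most other splits, at an adjusted p down to 2.63e-11. The smallest unadjusted camera p in another split was 1.07e-12 for sterol synthesis and 1.64e-07 for pancreatic progenitors. Every other split is unbalanced in control and TBZ libraries, so part of a real shift would remain in it. Calls of the acinar, sterol synthesis and pancreatic progenitor lists in other splits therefore cannot decide whether their shifts follow TBZ. For the 9 lists with a p as small in another split, a small camera p does not by itself mark the real grouping.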
